A study of Homo sapiens with 18 samples.

How the data were processed

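The sources were the series and sample labels, the deposited value tables and region lists of the 18 samples, the array's annotation and a table of current gene symbols. No paper or raw array file was used here. Per the labels, K562 lysate was incubated overnight in the cold with antibody on protein A/G magnetic beads, RNA was recovered by phenol/chloroform extraction and ethanol precipitation, and the sample was labelled with biotin by the standard Affymetrix procedure for gene ST arrays. The submitters name the PLIER algorithm for array summaries; its version and settings, how many arrays were summarised together, and the antibody lots are not given in the sources used here.

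The deposited value table holds log2 values, which the authors made from PLIER summaries, and their floor of exactly 4 fits the logarithm of a summary plus 16. Column values ran from 4 to 16.54 and array medians from 5.53 to 8.04. In the authors' region lists the deposited score falls in a straight line as the authors' p rises, to 0 at a p of 0.05. The deposited ratio is a fold of at least 2 made by the authors from the array values, and what stands below the line is not given in the sources used here. In the list attached to the array labelled T7 control replicate 1, that field is instead a signal, which equals the unlogged mean of the 3 deposited total input columns, with a median of 166.5. The authors' deposited p-value and adjusted p-value stand in 2 further fields, made by a test not given in the sources used here. In the authors' second version of the deposited lists these are given as -log10 of the same p and adjusted p. The region lists name hg19 per the labels, and their coordinates count from 1 here.

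The list attached to total input array 1 is named for the T7 control; of its 1809 probe sets 45.3% were lower in T7 than in total input and 4.04% higher. The list attached to the array labelled T7 control replicate 1 holds 19394 regions. Neither was used for gene results.

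The sample table, the design, the 13 comparisons, the alternatives and the gene lists were fixed before the data were examined. Arrays were quantile normalised because the quartiles of the deposited columns differed by more than the set limit of 0.1 (SD over arrays 0.856, 0.772 and 0.927). Of 28869 probe sets, 19310 carry one gene symbol, 1752 several and 7807 none, and 19279 of those with one symbol were found in the gene table by their gene identifier. Counts are over 18377 genes, each represented by its probe set with the highest mean over the 18 arrays. Differences were tested with limma (means of 6 groups over 18 arrays, 12 residual degrees of freedom, variance trend), adjusted by Benjamini-Hochberg over 28869 probe sets, and called at an adjusted p under 0.05. A value adjusted over the list alone uses only the members of that list. SE is the moderated standard error.

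Gene lists were written from general knowledge of gene families and reported targets, and the small nucleolar, zinc finger, oxidative phosphorylation and proteasome lists by patterns in the symbols, so that all their members are measured ones. They were tested with camera at a preset correlation of 0.01 between genes and again with a correlation estimated from the data, adjusted over 21 lists in each comparison. List shifts are medians of members minus the median of all genes. Measured members were 51 of 70 replication-dependent histones, 8 of 11 replacement histones, 34 of 35 AU-rich or ELAVL1-bound mRNAs, 22 of 23 GU-rich or CELF1-bound mRNAs, 57 of 79 ribosomal proteins, 20 of 22 translation factors and 0 of 28 mitochondrially encoded genes. Of the others 192 of 192 small nucleolar RNAs, 19 of 29 RNA polymerase III and spliceosomal RNAs, 3 of 10 nuclear long noncoding RNAs, 18 of 28 erythroid, 25 of 25 cell cycle, 24 of 25 DNA replication and 479 of 479 zinc finger genes were measured. So were 73 of 73 oxidative phosphorylation, 36 of 36 proteasome, 22 of 25 secretory, 17 of 22 cholesterol, 26 of 30 B lymphocyte, 20 of 20 hepatocyte and 14 of 15 epithelial genes, and the 4 mRNAs of the precipitated proteins.

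Named genes followed a rule. Against T7 they were the 10 largest rises and 5 largest falls with one symbol, an adjusted p under 0.05 and no overlap of the arrays, and the 2 members with the largest test statistic of each list that passed camera. In other comparisons they were the 5 largest rises and 3 largest falls, and the 4 proteins' own mRNAs were followed throughout. Other list members were named where a count was 5 or fewer. A single gene that this rule picked is left out of the text because it touches an item withheld for evaluation.

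Alternatives fixed beforehand were values as deposited, arrays centred on the median, the brighter probe sets alone, the mean of all probe sets of a gene, a robust variance, no variance trend, only the groups compared, a replicate block, the date batch as a fixed or random block or held constant, an estimated camera correlation and the omission of each array. Added after the data were seen were a common floor of 6.40, the list members and named genes without the array labelled T7 control replicate 1, its omission where T7 is not compared, and list tests within date batches. The date batch came from the dates in the array names of the labels and has 7 levels; PABPC1 and CELF1 arrays lie in batches of their own, and the correlation within batches was 0.517.

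In a self-test for SLBP against T7, differences were put into 200 of 18377 genes, with noise drawn at a spread pooled over all groups. Of these 2, 52, 86 and 96% were recovered at 1, 2, 3 and 4 log2 units, 3.28% of calls were false, and a histone list shift of 1.5 was found as 1.61. With no shift put in, camera called 0 of 21 lists. Tools were R 4.3.3, limma 3.58.1, statmod 1.5.0, GenomicRanges 1.54.1, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.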

Results

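K562 is a human erythroleukaemia cell line. RNA bound to 4 RNA-binding proteins in K562 was measured by RIP-chip, in which an antibody on magnetic beads pulls ribonucleoprotein complexes out of a cell lysate and the RNA in them is hybridised to an expression array. The proteins were ELAVL1 (HuR), which binds AU-rich elements, PABPC1, which coats poly(A) tails, CELF1, which binds GU-rich elements, and SLBP, which binds the stem-loop that ends replication-dependent histone mRNAs. A control RIP used an antibody against a bacteriophage coat protein (T7), and total cellular RNA served as input. Each of the 6 groups held 3 arrays, 18 in all. The labels define replicates as separate RIP runs and do not mention separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1, and genes were therefore tested with limma over all 18 arrays.

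The median deposited signal was 6.05, 6.91 and 7.06 log2 units on total input arrays 1, 2 and 3, and 5.53, 7.34 and 6.13 on the T7 control arrays. It was 7.77, 7.79 and 7.77 for ELAVL1, 8.04, 8.02 and 8.04 for PABPC1, 7.93, 7.85 and 7.86 for CELF1, and 7.69, 7.71 and 6.81 for SLBP. Probe sets at the floor of the value table made up 31.2% of T7 control array 1, 16.1% of T7 control array 3, 14.6% of total input array 1 and 13.3% of SLBP array 3, and at most 2.56% of any other array. Across probe sets, which are not independent replicates, arrays correlated with the others of their group at a mean r of 0.98 for ELAVL1, 0.97 to 0.98 for CELF1, 0.90 to 0.95 for PABPC1, 0.83 to 0.91 for SLBP and 0.84 to 0.91 for total input. The T7 control arrays 1 and 2 correlated at r = 0.43, arrays 1 and 3 at 0.74, and arrays 2 and 3 at 0.67.

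The array labelled T7 control replicate 1 stood apart in cell-type markers. Its 26 measured B lymphocyte markers had a median 3.54 log2 units above the total input mean, against -0.69 and -0.11 on T7 control arrays 2 and 3. CD79A, the B cell receptor subunit, reached 13.58 log2 units there and at most 9.25 on the other 17 arrays, and the B lineage factor PAX5 reached 13.21 against at most 8.58. The 18 measured erythroid genes lay 2.43 log2 units below input on that array (-2.43), against medians of -0.43 to 1.18 on the others: embryonic globin HBE1 and the erythroid factor GATA1 were at its floor, below 6.40, against at least 11.85 and 7.32 elsewhere. Of the erythroid genes 8 of 18 were at the floor there, and with all values raised to that level the median was still -2.43. Hepatocyte and epithelial markers had medians of 0.22 and -0.30. Gene counts and called lists against the T7 control are therefore also given without this doubted array, as are named genes whose fold moved by more than 1.5 times. Leaving out each array of the groups compared was planned, and giving this omission throughout was chosen after seeing the data.

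**Figure D1:**
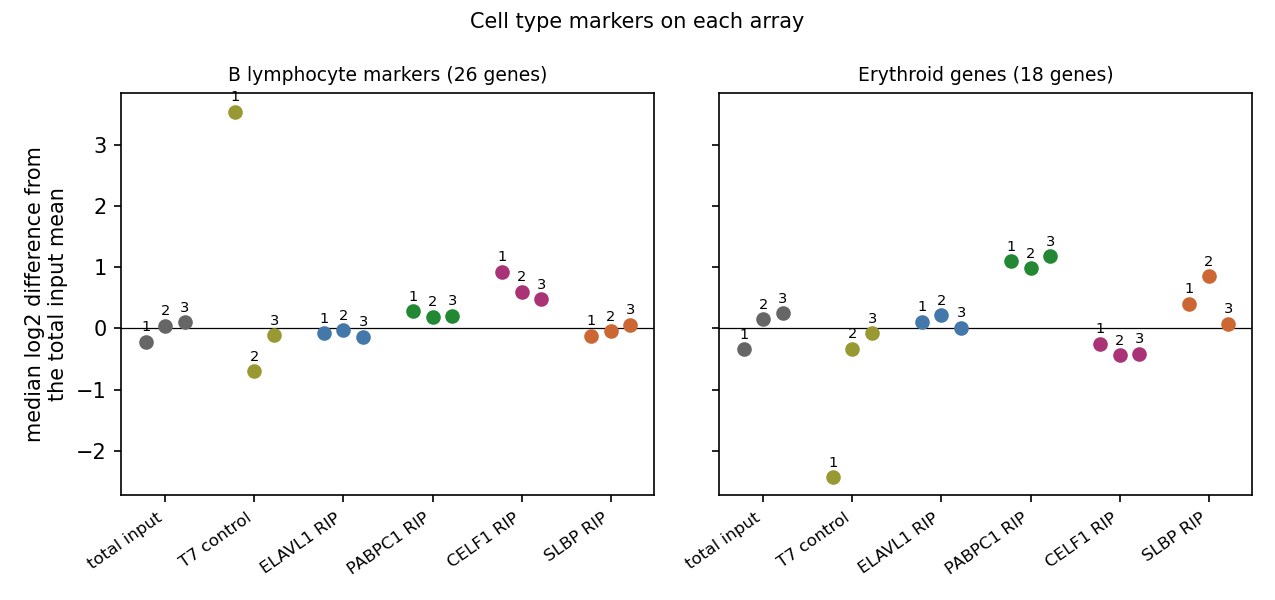
Median log2 difference from the total input mean for the 26 B lymphocyte markers and the 18 erythroid genes (vertical axes), by group (horizontal axes). Each point is 1 array and carries its replicate number; T7 control array 1 lies at 3.54 in the first panel and at -2.43 in the second.

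The ELAVL1 RIP was compared with the T7 control to ask which RNAs were higher in the ELAVL1 complexes than in a mock precipitation. ELAVL1's own mRNA was higher by 4.03 log2 units (SE 0.457, n = 3 and 3 arrays, adjusted p = 6.7e-06), a 16.3-fold difference. TSPAN13 showed the largest rise, 46.1-fold (5.53, SE 0.572, adjusted p = 2.67e-06), followed by LAPTM4B (5.04) and HSPA13 (4.97). SCUBE2, CNIH1, LYPLA1, LAMTOR3, GINS1, ZMPSTE24 and CA1 rose by 4.92 to 4.70. Without the doubted array TSPAN13 was at 4.65 (25.2-fold), behind HSPA13 at 5.02 (32.5-fold). LAPTM4B was then at 4.09, LYPLA1 at 4.01, ZMPSTE24 at 3.95 and LAMTOR3 at 3.92. The largest falls were in SGCB (-6.01, SE 0.327, adjusted p = 1.37e-08), RBM15B (-5.75), FREM2 (-5.49), SLC29A3 (-5.39) and PRDM8 (-5.35). With a common floor SCUBE2 was at 4.02 and LAMTOR3 at 3.95 (2 and 1 T7 arrays at the floor), and FREM2 at -4.37. In total 4262 genes were higher and 2450 lower of 18377, around a median difference of 0.13 over all genes. With values as deposited, where that median was 1.60, the split was 9204 to 202.

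Genes of endoplasmic reticulum chaperones and secretion rose as a group in the ELAVL1 RIP: 13 of 22 were higher and 1, P4HB, lower (14 and 1 adjusted over the list alone). Their median lay 1.53 above that of all genes (camera adjusted p = 0.000779, adjusted p = 0.145 with an estimated correlation). The signal peptidase subunit SPCS1 rose by 3.34 and the translocon-associated SSR1 by 2.36. Of 34 measured mRNAs with AU-rich elements or reported ELAVL1 binding, 14 were higher, among them ELAVL1 itself and cyclin A2, CCNA2 (3.70, and 3.05 without the doubted array). In that list 2, BCL2 and PTGS2, were lower (14 and 2 adjusted over the list alone). That list lay 0.48 above all genes (camera adjusted p = 0.0428, adjusted p = 0.145 with an estimated correlation; 0.177 without T7 control array 2 and 0.062 with the mean of all probe sets of a gene). Of 192 small nucleolar RNAs, 39 were lower and 18 higher (38 and 18 adjusted over the list alone). Their median was -0.58 relative to all genes (camera adjusted p = 0.0208, adjusted p = 0.545 with an estimated correlation; -0.31 and adjusted p = 0.067 with a common floor). SNORA55 (3.09, and 2.31 without the doubted array) and SNORA29 (2.16, and 1.15 with a common floor), the members with the largest test statistics, went against the list. Members named for a count of 5 or fewer were chosen after their values were seen, here and below.

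The remaining lists did not pass camera in this comparison. Adjusted p was 0.0721 for the 22 mRNAs with GU-rich elements or reported CELF1 binding (10 higher, 1 lower; 0.0276 without the doubted array, adjusted p = 0.205 with an estimated correlation), 0.0756 for 57 ribosomal protein genes (9 and 14), 0.0756 for 36 proteasome genes (16 and 5) and 0.0721 for B lymphocyte markers (2 and 3, with a relative median of -0.96). It was 0.103 for cell cycle genes, 0.123 for erythroid genes, 0.248 for replacement histones, 0.365 for cholesterol synthesis, 0.538 for replication-dependent histones, 0.612 for 479 C2H2 zinc finger genes and 0.706 for nuclear-encoded oxidative phosphorylation genes. Leaving out that array gave 5810 called genes, and kept the secretory (11 higher, adjusted p = 0.00312), AU-rich (12 higher, 0.0276) and small nucleolar lists (29 lower, 0.0449; adjusted p = 0.0716, 0.316 and 0.626 with an estimated correlation). With the date batch as a fixed block 4799 genes were called, and those 3 lists shifted by 1.52, 0.89 and -0.88. No T7 array shares a batch with ELAVL1, so this contrast is bridged by total input array 1 alone, with the doubted array among the 2 T7 arrays of batch 1. As a random block it left 5829.

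PABPC1 was compared with the T7 control to find RNAs held by the cytoplasmic poly(A)-binding protein. RMRP, the RNA of RNase MRP, was lower by 4.22 log2 units (-4.22, SE 0.408, n = 3 and 3 arrays, adjusted p = 1.66e-06) and the spliceosomal RNU5E-1 was at -3.55. Of these RNAs, 12 of 19 of the RNA polymerase III and spliceosomal class were lower and the rest not called (12 lower adjusted over the list alone). Of 192 small nucleolar RNAs, 46 were lower, with SNORD13P3 at -4.14 and SNORD33 at -3.89, and 4 higher (46 and 4 adjusted over the list alone). These lists lay at -2.65 and -1.14 relative to all genes, each with camera adjusted p = 1.31e-09; adjusted p = 0.264 and 0.121 with an estimated correlation. They lay at -2.32 and -0.77, with 12 and 42 members lower, without the doubted array.

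Among nuclear-encoded oxidative phosphorylation genes 51 of 73 were higher in the PABPC1 RIP and 22 not called (55 adjusted over the list alone), led by UQCR10 of complex III (3.58) and SDHD of complex II (3.09, and 2.29 on its second probe set). Their relative median was 1.2 (camera adjusted p = 1.31e-09, adjusted p = 0.179 with an estimated correlation). For the proteasome 25 of 36 were higher and 1, PSMB11, lower (26 and 1 adjusted over the list alone). PSMA2 rose by 4.48 (SE 0.354) and PSMB7 by 2.61, and the relative median was 1.39 (camera adjusted p = 2.19e-06, adjusted p = 0.179 with an estimated correlation). Erythroid genes were higher in 15 of 18 (15 adjusted over the list alone), among them the heme enzyme gene UROD and the band 3 gene SLC4A1, both by 2.97. The relative median of 1.69 (camera adjusted p = 0.000891, adjusted p = 0.455 with an estimated correlation) became 1.18 without the doubted array, on which erythroid genes lay at -2.43, and UROD was then at 2.36. Secretory genes were higher in 14 of 22 (15 adjusted over the list alone; relative median 1.21, camera adjusted p = 0.000891, adjusted p = 0.179 with an estimated correlation), with SSR4 at 4.03 and the KDEL receptor gene KDELR1 at 2.32. Cholesterol synthesis genes were higher in 9 of 17 (11 adjusted over the list alone; 1.27, camera adjusted p = 0.00949, adjusted p = 0.315 with an estimated correlation, 0.63 without that array), with SC5D at 2.98 and INSIG1 at 2.56. Omitting that array left 47 oxidative phosphorylation, 24 proteasome and 11 secretory genes higher. Camera adjusted p was then 4.07e-09, 3.75e-07 and 0.00395, and 0.101, 0.0334 and 0.0652 with an estimated correlation. All but the erythroid list also lay lower in T7 than in input, and these shifts include that deficit.

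Ribosomal protein genes were higher in 26 of 57 and lower in 2, RPS23 and RPL26 (27 and 2 adjusted over the list alone), with RPS28 at 2.92 (1.84 and 1.88 on its other 2 probe sets) and RPS16 at 2.72. Their relative median was 0.40 (camera adjusted p = 0.000891, adjusted p = 0.455 with an estimated correlation) but -0.04 with arrays centred on the median and -0.04 with values as deposited. Translation factor genes were higher in 13 of 20 and lower in 1, EEF1B2 (13 and 1 adjusted over the list alone; relative median 0.50, camera adjusted p = 0.0388, adjusted p = 0.337 with an estimated correlation), with EIF3L at 2.24 and EIF4A2 at 1.64, whose second probe set gave 0.89 (adjusted p = 0.153). That call ended without T7 control array 2 (0.23, 0.186), PABPC1 array 1 (0.0687) or PABPC1 array 2 (0.0889), and with median centring (0.201); the shift was 0.79 without PABPC1 array 3. Omitting T7 control array 1 left 27 ribosomal protein genes higher at 0.54 (0.000157) and 10 translation factors at 0.65 (0.0421). With an estimated correlation adjusted p was 0.415 and 0.38. B lymphocyte markers were lower in 4 of 26 (TNFRSF13B, CD79A, PAX5 and CD48) and higher in 1, CD53 (2 and 1 adjusted over the list alone; -0.88, camera adjusted p = 0.0476, adjusted p = 0.835 with an estimated correlation). The same markers without that array were higher in 9 and lower in 1, at 0.37 (adjusted p = 0.318), and CD79A went from -3.03 to -1.41; without PABPC1 array 3 the list's adjusted p was 0.083.

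The largest single rises in the PABPC1 RIP were in LAMTOR3 (5.36 log2 units, SE 0.585, adjusted p = 4.03e-06), POPDC3 (5.15), CYBRD1 (4.64) and LSM5 (4.59). PSMA2, the histone gene H2AC25, C15orf61, DNAJC19 (3.60 on its second probe set), PCTP and MPC2 rose by 4.48 to 4.40. LAMTOR3 was at 4.50 without the doubted array, behind POPDC3 at 5.06 and C15orf61 at 4.84, with H2AC25 at 3.65 and MPC2 at 3.61. With a common floor LAMTOR3 was at 4.56, POPDC3 at 3.73 and C15orf61 at 3.82 (1, 2 and 1 T7 arrays at the floor), and FREM2 at -4.37. The potassium channel gene KCNC2 (-5.55), FREM2 (-5.11), PLA2G2D (-5.11), SOX1 (-5.04) and RBM15B (-5.00) fell most. Gene counts were 4867 higher and 2073 lower around a median difference of 0.36 (11701 to 225 around 2.28 with values as deposited), and 6033 genes in all without the doubted array. Replication-dependent histones (10 higher, 6 lower) did not pass camera (adjusted p = 0.459, with a downward test against a relative median of 0.05), nor did AU-rich mRNAs (0.557), GU-rich mRNAs (0.178), cell cycle (0.114) and DNA replication genes (0.16) or zinc finger genes (0.681). PABPC1 arrays lie in date batches of their own, so batch and group can be separated only by a random block, under which 4632 genes were called.

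CELF1 was compared with the T7 control in the same way. ERMP1, a metallopeptidase gene, rose 57.9-fold (5.86, SE 0.455, n = 3 and 3 arrays, adjusted p = 1.62e-07), followed by MFSD1 (5.62), FGF13 (5.62), LRP12 (5.43), TSPAN13 (5.33), PDSS2 (5.31), ELOVL7 (5.21), OR51B5, LINC01560 and SIAH1 (5.07). FGF13 was at 4.72, TSPAN13 at 4.46 and OR51B5 at 4.18 without the doubted array, and ERMP1 stayed highest of the genes named here (5.36). SGCB (-6.66, SE 0.327), SOX1 (-5.52), TMEM42 (-5.42), MSX2 (-5.31, and -4.69 without that array) and KCNC2 (-5.17) fell most. With a common floor PDSS2 was at 4.53 (2 T7 arrays at the floor), SGCB at -5.60 and MSX2 at -4.60. In total 4346 genes were higher and 2504 lower around a median of 0.15 (9776 to 184 around 1.67 with values as deposited).

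Small nucleolar RNAs fell as a group: 51 of 192 were lower and 20 higher (56 and 20 adjusted over the list alone), at -0.89 relative to all genes (camera adjusted p = 0.000195, adjusted p = 0.359 with an estimated correlation). SNORD33 was at -4.07 and SCARNA17 at -3.84, with -1.51 on its second probe set. RNA polymerase III and spliceosomal RNAs were lower in 8 of 19, with RNU4-1 at -1.97 and the telomerase RNA TERC, which the list holds as a further structured RNA, at -2.64 (-2.03 without the doubted array), and higher in 1, RNU5F-1 (9 and 1 adjusted over the list alone; -1.18, camera adjusted p = 0.0424, adjusted p = 0.972 with an estimated correlation). That call ended without that array (-0.72, 0.0706), T7 control array 3 (0.184) or CELF1 array 1 (0.071), and with a common floor (0.0589), and the shift was -2.15 without T7 control array 2. Of the 22 mRNAs with GU-rich elements or reported CELF1 binding, 10 were higher and 3 lower (13 and 3 adjusted over the list alone), at 1.18 (camera adjusted p = 0.0936, adjusted p = 0.359 with an estimated correlation). Without the doubted array this list passed, with 11 higher at 1.02 (adjusted p = 0.0443). So did B lymphocyte markers, with 10 of 26 higher at 0.89 (adjusted p = 0.0115) against 2 with all arrays (0.755). The small nucleolar list was then at -0.57 (0.00239). Each of these lists had adjusted p = 0.313 with an estimated correlation.

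Oxidative phosphorylation genes (31 higher, 6 lower; camera adjusted p = 0.0745), secretory genes (11 and 2; 0.0936), AU-rich mRNAs (15 and 3; 0.106), ribosomal protein genes (13 and 21; 0.123), replacement histones (5 of 8 higher; 0.23), erythroid genes (6 and 1; 0.414), replication-dependent histones (16 and 5; 0.746) and proteasome genes (14 and 7; 0.768) did not pass in the CELF1 RIP, nor did translation factors (4 of 20 lower; 0.587). The CELF1 arrays share a batch that holds no other group. With batch as a random block 2920 genes were called against 6850 without it. Leaving out the doubted array gave 6429.

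SLBP was compared with the T7 control to ask whether histone mRNAs stood out. Replication-dependent histone genes were higher in 23 of 51, and the other 28 were not called (40 higher adjusted over the list alone), at 1.65 log2 units above the median of all genes (camera adjusted p = 9.09e-11, adjusted p = 0.56 with an estimated correlation). H2AC11 rose 13.1-fold (3.71, SE 0.643, n = 3 and 3 arrays, adjusted p = 0.000868) and H3C7 5.76-fold (2.53, SE 0.417, adjusted p = 0.000569). These genes were at 2.67 (6.36-fold) and 2.42 (5.35-fold) without the doubted array. Replacement histones, whose mRNAs are polyadenylated, were higher in 2 of 8 (camera adjusted p = 0.372).

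The histone shift was uneven across arrays. Over the total input mean the 51 genes lay at 0.11 and 0.15 on SLBP arrays 1 and 2 and at 2.37 on SLBP array 3, and at -1.24, -0.36 and -0.66 on the T7 control arrays. Without SLBP array 3 the shift against T7 was 0.81 (adjusted p = 0.000286), and without the doubted array it was 1.24, with 16 of 51 higher (31 adjusted over the list alone). With the date batch as a fixed block it was 0.88 (adjusted p = 0.000127), and within batch 1, which holds SLBP arrays 1 and 2 and T7 control arrays 1 and 2, it was 0.88 (adjusted p = 6.69e-05). Those SLBP arrays lay 1.22 above the doubted T7 array but 0.50 above T7 control array 2. These p-values are at the preset correlation, and with an estimated one the call was already lost with all arrays (adjusted p = 0.56).

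**Figure D2:**
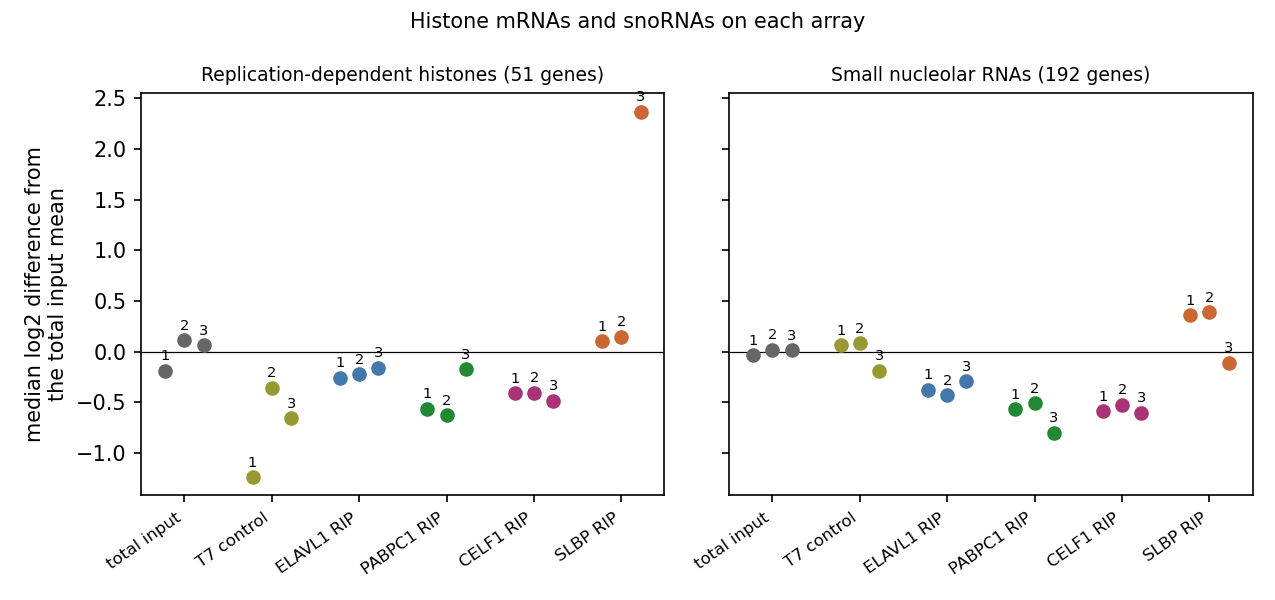
Median log2 difference from the total input mean for the 51 measured replication-dependent histone genes and the 192 small nucleolar RNAs (vertical axes), by group (horizontal axes). Each point is 1 array with its replicate number; SLBP array 3 lies at 2.37 for histones, SLBP arrays 1 and 2 at 0.11 and 0.15, and the PABPC1 arrays at -0.57, -0.51 and -0.80 for small nucleolar RNAs.

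Outside histones, the largest rises in the SLBP RIP were in RPS6KA6 (5.86, SE 0.434), CCNJ (56.3-fold, 5.82, SE 0.323, adjusted p = 3.85e-09), TSPAN7 (5.59) and ALDH6A1, at 5.56 on one probe set but -0.48 on the other (adjusted p = 0.566). ELFN2, C1orf115, SLC36A4, the globin gene HBM, SLC17A3 and SLCO2A1 rose by 5.40 to 4.98. SGCB (-6.46), the AMPK subunit gene PRKAA2 (-6.37), TINCR (-6.22), KCNC2 (-6.01) and ZNF302 (-5.91) fell most. With a common floor RPS6KA6, TSPAN7, C1orf115, HBM and SLCO2A1 were at 4.37, 4.52, 4.68, 4.28 and 4.36. Of the T7 arrays 2, 2, 2, 2 and 1 were at the floor for these rises. With that floor the 5 falls were at -5.60, -5.65, -5.11, -5.34 and -4.99. Counts were 1386 higher and 1106 lower around a median of 0.14 (4797 to 266 around 1.09 with values as deposited). These counts depended on arrays and groups, with 6518 genes called without T7 control array 2, 1883 without the doubted array, 1578 without SLBP array 2, and 138 with only the groups compared. With the date batch as a fixed block 3475 genes were called, and as a random block 3806. Within batch 1 limma called 0, with 1292 at an unadjusted p under 0.05.

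Oxidative phosphorylation genes were higher in 17 of 73 and lower in 1, NDUFS8 (23 and 2 adjusted over the list alone; relative median 0.61, camera adjusted p = 4.09e-05, adjusted p = 0.56 with an estimated correlation), with ATP5MC3 at 3.69 (2.93 without the doubted array) and NDUFS7 at 2.41. Erythroid genes were higher in 9 of 18 and lower in 1, EPB42 (13 and 1 adjusted over the list alone; 1.63, camera adjusted p = 0.000229, adjusted p = 0.56 with an estimated correlation), with KLF1 at 2.24 and LMO2 at 2.02. Without the doubted array, on which they lay at -2.43, 3 were higher at 0.73. Oxidative phosphorylation genes were then higher in 14 at 0.54. Ribosomal protein genes were higher in 7 of 57 (7 adjusted over the list alone; 0.34, camera adjusted p = 0.00292, adjusted p = 0.589 with an estimated correlation), with FAU at 2.51 and RPS16 at 1.56. They lay at -0.02 without T7 control array 2 (0.318) at 0.12 with median centring (0.635), and at 0.46 without the doubted array. Under a fixed batch block, where that array is 1 of 2 T7 arrays, these 3 lists lay at 0.75, 1.92 and 0.34.

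A further 6 lists passed camera in the SLBP RIP at a larger adjusted p, and each lost its call without the doubted array. Cell cycle genes were higher in 4 of 25, CCNA2, CDC20, PLK1 and AURKB (6 adjusted over the list alone; 0.69, camera adjusted p = 0.0148, adjusted p = 0.637 with an estimated correlation, 0.08 and 0.524 without that array). DNA replication genes were higher in 3 of 24, TYMS, RFC4 and GINS1 (0.50, 0.0412, adjusted p = 0.637 with an estimated correlation, 0.17 and 0.525 without that array). Proteasome genes were higher in 4 of 36 and lower in 2 (0.50, 0.0221, adjusted p = 0.589 with an estimated correlation, 0.30 and 0.0941 without that array), with PSMC2 at 2.04 (1.21 without it) and PSMB1 at 1.71. Of the secretory and cholesterol genes 1 each was higher, SSR4 (1.71; list 0.46, 0.0466, adjusted p = 0.56 with an estimated correlation, 0.28 and 0.184 without that array) and DHCR7 (1.15; list 0.74, 0.0245, adjusted p = 0.56 with an estimated correlation, 0.39 and 0.0871 without that array). HSPA5 (1.32, adjusted p = 0.0618, and 0.67 without that array) and EBP (1.02, 0.0535), the next members of these lists, did not pass. B lymphocyte markers were lower in 2 of 26, CD79A (-3.71) and HLA-DMB (-1.78, and -1.19 without that array; -1.74 and not called on its second probe set, adjusted p = 0.122), at -1.25 (camera adjusted p = 0.00562, adjusted p = 0.637 with an estimated correlation). Without that array the list lay at 0.04 (0.384), with 4 higher, and CD79A at -2.08.

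Several of these calls also rested on other single arrays. CCNA2 (1.61, adjusted p = 0.0189) no longer passed without the doubted array (1.0, 0.0639), SLBP array 2 (0.0538) or SLBP array 3 (0.0665), nor CDC20 (1.49) without the first (0.84, 0.0531), SLBP array 1 (0.0637) or SLBP array 2 (0.0775). GINS1 (1.41) was lost without the doubted array (1.08, 0.072), SLBP array 1 (0.0798) or SLBP array 3 (0.0657), SSR4 without the first (1.41, 0.0524) or SLBP array 2 (0.0625), and DHCR7 without any SLBP array (0.119, 0.12 and 0.057) or the first (0.86, 0.154). The cell cycle list also failed without SLBP array 1 (0.0884), and the DNA replication list without SLBP arrays 1 or 2 (0.0884 and 0.0704). So did the proteasome list without T7 control array 2 (0.0718), and the cholesterol list without T7 control array 2 (0.0783) or SLBP array 1 (0.0728). The secretory list failed without T7 control array 2 (0.17), SLBP array 1 (0.0728) or SLBP array 3 (0.146), and with median centring (0.0888). Under a fixed batch block these lists lay at 0.92 for the cell cycle, 0.95 for DNA replication, 0.54 for the proteasome, 0.64 for secretion, 0.79 for cholesterol and -1.55 for B lymphocyte markers. That block reduces the contrast to batch 1, where the doubted array is 1 of 2 T7 arrays, so these values lean on it more. Small nucleolar RNAs (21 higher, 2 lower; camera adjusted p = 0.335), AU-rich mRNAs (5 higher; 0.125) and translation factors (2 higher; 0.171) did not pass with all arrays. The first 2 did without the doubted array (0.0399 and 0.0296; adjusted p = 0.434 for each with an estimated correlation). Of the 19 RNA polymerase III and spliceosomal RNAs, 19 were not called by limma.

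The mRNAs of the 4 precipitated proteins were followed in every comparison. ELAVL1 mRNA was also higher against T7 in the PABPC1 (2.94, adjusted p = 0.000107), CELF1 (3.24, 4.21e-05) and SLBP RIPs (1.46, 0.0468), the last lost without T7 control array 3 (0.88, 0.166), SLBP array 1 (0.11) or SLBP array 3 (0.144) and at 2.02 (0.00255) without the doubted array. PABPC1 mRNA was higher in the ELAVL1 (1.82, 0.000291) and PABPC1 RIPs (1.67, 0.000506), and in the CELF1 RIP without the doubted array (0.82, 0.0204, against 0.42, 0.303). CELF1 mRNA was higher in the CELF1 RIP (0.99, SE 0.345, adjusted p = 0.035) and lost its call without the doubted array (0.81, 0.0954), T7 control array 3 (0.0508) or any CELF1 array (0.0669, 0.0931 and 0.0996). In the PABPC1 RIP it was lower (-1.05, 0.0249) and at 1.67 with values as deposited, where the median of all genes was 2.28. The call was lost without T7 control array 3 (0.0555), PABPC1 array 1 (0.0503) or PABPC1 array 3 (0.0799). SLBP mRNA was called in no T7 comparison by limma. It was at -0.58 in the SLBP RIP (SE 0.479, adjusted p = 0.447), and at 0.39 there with values as deposited, where the median of all genes was 1.09. As a list, these 4 mRNAs did not pass camera in the ELAVL1 (0.0892; 0.0456 without the doubted array, adjusted p = 0.205 with an estimated correlation), PABPC1 (0.681), CELF1 (0.23) or SLBP comparison (0.813).

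Several lists passed camera in none of the 4 T7 comparisons with all arrays. Hepatocyte markers were higher in 4, 4, 4 and 3 of 20 in the ELAVL1, PABPC1, CELF1 and SLBP RIPs (camera adjusted p = 0.935, 0.681, 0.919 and 0.546), and epithelial markers in 3, 4, 2 and 1 of 14 (0.797, 0.85, 0.919 and 0.668). Nuclear-retained long noncoding RNAs, with 3 measured, gave 0.548, 0.7, 0.919 and 0.813. Zinc finger genes were higher in 110, 114, 103 and 22 of 479 (0.612, 0.681, 0.919 and 0.39). No mitochondrially encoded gene was measured (0 of 28 list members).

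Each RIP was also set against total input, which shows enrichment over the cell's RNA rather than over a mock precipitation. In the ELAVL1 RIP, AU-rich mRNAs were higher in 10 of 34 (13 adjusted over the list alone) at 0.60 relative to all genes (camera adjusted p = 0.00307, adjusted p = 0.114 with an estimated correlation), and ELAVL1's own mRNA rose 6.16-fold (2.62, SE 0.457, adjusted p = 0.000891). The AU-rich list lay at 0.81, 0.75 and 0.73 over total input on the ELAVL1 arrays and higher, at 1.21, 1.07 and 0.96, on the CELF1 arrays. Ribosomal protein genes were lower in 25 of 57 and higher in 2, RPL23 and RPL22 (33 and 2 adjusted over the list alone; -0.95, camera adjusted p = 2.02e-12, adjusted p = 0.215 with an estimated correlation). Oxidative phosphorylation genes were lower in 24 and higher in 6 of 73 (29 and 7 adjusted over the list alone; -0.94, 1.83e-06, adjusted p = 0.343 with an estimated correlation). Small nucleolar RNAs (16 lower, 4 higher; -0.47, 0.00307, adjusted p = 0.343 with an estimated correlation), RNA polymerase III and spliceosomal RNAs (5 of 19 lower; -1.07, 0.00185, adjusted p = 0.701 with an estimated correlation) and translation factors (5 of 20 lower; -0.53, 0.0439, adjusted p = 0.343 with an estimated correlation) also fell. The last call ended without total input array 1 (-0.33, 0.0759) or the doubted array (0.0541), and that on spliceosomal RNAs without total input array 1 (-0.54, 0.0759). SAMD5 (5.39, and 3.94 with a common floor), VAMP5 (4.92) and NXNL2 (4.41, 3.78 with that floor) rose most, followed by KRT2 and SLC44A1, and GAREM1 (-6.47, and -5.38 with that floor), CYRIA (-5.25) and CSTL1 (-5.03) fell most.

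With the date batch as a fixed block the ELAVL1 lists against input lay at 0.71 for AU-rich mRNAs, -1.30 for ribosomal proteins, -1.21 for oxidative phosphorylation, -0.65 for small nucleolar RNAs, -2.08 for spliceosomal RNAs and -0.83 for translation factors. Batch 2 holds the ELAVL1 arrays and a single input array, total input array 1, so these shifts rest on that array. Within batch 2 10590 genes were called, with only the ELAVL1 arrays to supply the spread, against 2100 higher and 1149 lower with all batches (5107 to 149 with values as deposited), 5048 with the fixed block and 4822 with the random one. Leaving out 1 ELAVL1 array left 1886 to 1913 genes.

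In the PABPC1 RIP against input, RNA polymerase III and spliceosomal RNAs were lower in 14 of 19 and the rest not called (17 lower adjusted over the list alone; -2.53 relative to all genes, camera adjusted p = 5.01e-16, adjusted p = 0.201 with an estimated correlation). RNU5D-1 was at -4.87 (SE 0.581). Small nucleolar RNAs were lower in 39 of 192 (39 adjusted over the list alone; -0.79, camera adjusted p = 2.24e-12, adjusted p = 0.0474 with an estimated correlation). Replication-dependent histones were lower in 12 of 51 and higher in 1, H3C8 (13 and 2 adjusted over the list alone; -0.72, 7.33e-05, adjusted p = 0.926 with an estimated correlation). Oxidative phosphorylation genes were higher in 24 of 73 and lower in 1, ATP5PF (29 and 1 adjusted over the list alone; 0.55, 9.95e-05, adjusted p = 0.754 with an estimated correlation). NDUFAF3 (3.86), ADCK1 (3.68), SGCB (3.65), KCNMA1 and SPRR2D rose most, and NWD2 (-5.00), RNU5D-1 and CRYGN (-4.67) fell most; a common floor put ADCK1 at 3.02, SGCB at 2.85, SPRR2D at 2.13 and NWD2 at -4.37. Counts were 2713 higher and 1134 lower around a median of 0.30 (10128 to 172 around 1.81 with values as deposited). ELAVL1 mRNA was higher (1.53, adjusted p = 0.0247) and CELF1 mRNA lower (-1.22, 0.0193, and 1.01 with values as deposited, where the median of all genes was 1.81). The first call ended without total input arrays 1 or 3 (0.0629 and 0.0764) or PABPC1 arrays 1 or 3 (0.0501 and 0.0777), and the second without total input arrays 2 or 3 (0.0756 each) or PABPC1 array 3 (0.0703). PABPC1's own mRNA did not pass (0.76, 0.0981). It did without the doubted array (0.74, 0.0233), which enters only scaling and spread here. With median centring it lay below the median of all genes. Leaving out total input array 1 gave 2540 genes, PABPC1 array 1 2564 genes, and a random batch block 1997.

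**Figure D3:**
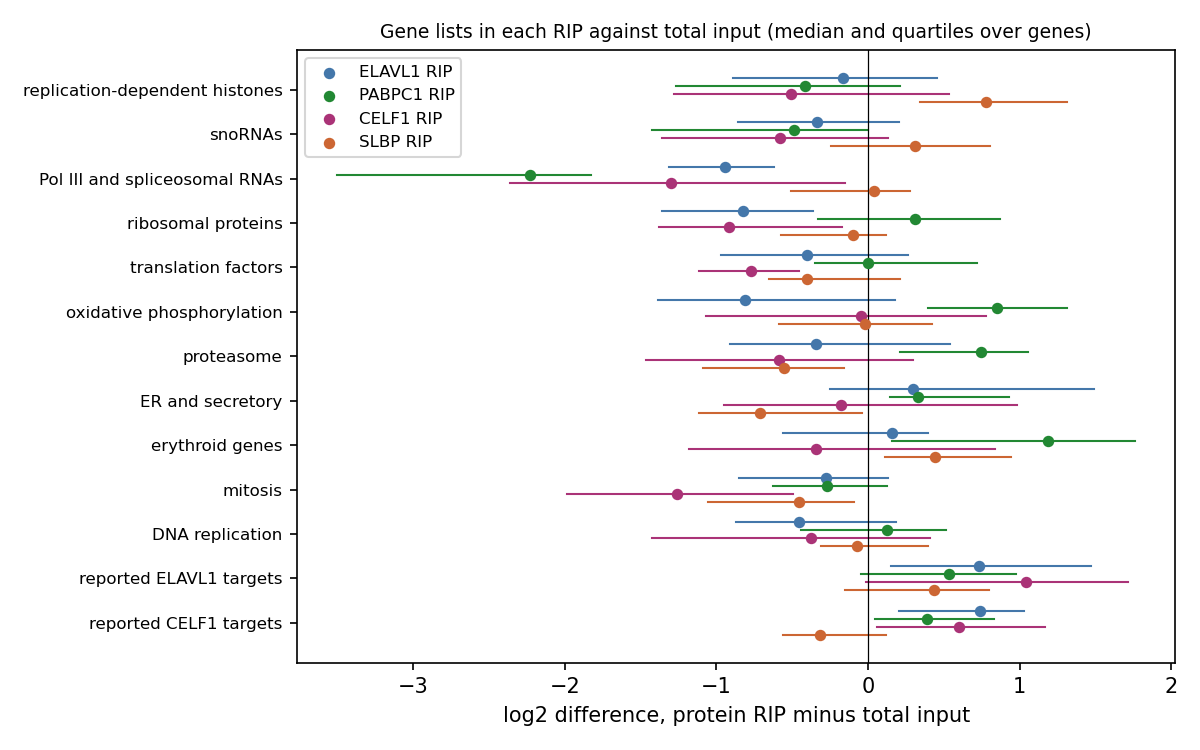
Log2 difference of each RIP from total input (horizontal axis) for 13 gene lists (vertical axis). A point is the median over the genes of a list and a line runs from its lower to its upper quartile; RNA polymerase III and spliceosomal RNAs have a median of -2.23 in the PABPC1 RIP and replication-dependent histones one of 0.78 in the SLBP RIP.

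In the CELF1 RIP against input, TMEM14A (4.91, SE 0.339), NXNL2 (4.85), the cyclin-domain gene CNTD1 (4.72), UNC5D (4.61) and CADPS2 (4.60) rose most, and STIM2, a calcium sensor gene (-5.30), AKR1E2 (-4.98) and KCNQ3 (-4.91) fell most; a common floor put NXNL2, CNTD1, UNC5D and CADPS2 at 4.23, 3.40, 3.55 and 3.16. Ribosomal protein genes were lower in 29 of 57 and higher in 6 (35 and 7 adjusted over the list alone; -1.04, camera adjusted p = 2.88e-07, adjusted p = 0.34 with an estimated correlation). Small nucleolar RNAs were lower in 40 and higher in 7 (40 and 7 adjusted over the list alone; -0.70, 7.06e-05, adjusted p = 0.339 with an estimated correlation), and cell cycle genes lower in 10 of 25 and higher in 1, AURKB (10 and 1 adjusted over the list alone; -1.38, 8.02e-05, adjusted p = 0.546 with an estimated correlation). Translation factors (7 of 20 lower; -0.89, 8.02e-05, adjusted p = 0.255 with an estimated correlation), spliceosomal and RNA polymerase III RNAs (10 lower; 1, RNU5F-1, higher; -1.42, 0.000354, adjusted p = 0.546 with an estimated correlation) and proteasome genes (10 lower; 1, PSMD10, higher; -0.71, 0.00196, adjusted p = 0.462 with an estimated correlation) fell too. Counts were 3065 higher and 1856 lower around a median of 0.12 (5996 to 196 around 1.23 with values as deposited), 3198 genes in all without CELF1 array 1, and 1488 with batch as a random block. ELAVL1 mRNA was higher (1.84, adjusted p = 0.00735) and CELF1 mRNA at 0.82 (0.0951). GU-rich mRNAs (6 of 22 higher, 3 lower; 0.335) and AU-rich mRNAs (15 of 34 higher, 4 lower; 0.93 relative to all genes, 0.0833) did not pass.

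In the SLBP RIP against input, 5 of 51 replication-dependent histone genes were higher (5 adjusted over the list alone) at 0.74 (camera adjusted p = 0.000294, adjusted p = 0.885 with an estimated correlation). They were the core histone gene H3C3 and the linker histone genes H1-5, H1-3, H1-4 and H1-1. Without SLBP array 3 the shift was 0.02 (0.991), and with the date batch as a fixed block -0.10 (0.946). Proteasome genes were lower in 4 of 36 (9 adjusted over the list alone; -0.59, camera adjusted p = 0.0118, adjusted p = 0.885 with an estimated correlation; 0.0646 without total input array 3; -0.49 with the fixed block). Of the secretory genes SSR1 and DNAJB9 were lower (-0.74, 0.0481, adjusted p = 0.885 with an estimated correlation; -0.83 with the fixed block), a call lost without total input array 2 (0.112), total input array 3 (0.109), SLBP array 1 (0.0674) or SLBP array 2 (0.101). VAMP5, a SNARE gene (5.57, SE 0.275), C1orf115 (5.37), MSANTD1 (5.35), CNTD1 (5.20) and UNC5D (5.05) rose most, and TINCR (-6.18), PRKAA2 (-5.83) and LGI2 (-5.77) fell most, and a common floor put the last 3 rises at 4.03, 3.88 and 3.99 and these falls at -5.08, -5.11 and -4.96. Counts were 902 higher and 1067 lower around a median of 0.03, 883 to 207 with values as deposited and 518 to 951 with median centring. In all 1148 genes were called without total input array 1 and 1157 without SLBP array 2. With batch as a fixed block 2134 were called, as a random block 2671, and within batch 1 4989. SLBP mRNA was at -0.32 (0.806).

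The T7 control was set against total input to describe the background of the precipitation. SGCB rose 84.0-fold (6.39, SE 0.327), VAMP5 by 6.37, KCNC2 by 5.98, EID3 by 5.82 and ANGEL1 by 5.78, while LGI2 fell by 5.85 on the log2 scale, SLC36A4 by 5.39 and CCNJ by 5.28. A common floor put SGCB at 5.60, KCNC2 at 5.34 and LGI2 at -4.96. SGCB and KCNC2 were among the largest falls, and SLC36A4 and CCNJ among the largest rises, in the SLBP RIP against T7. Of all genes 1392 were higher and 2160 lower around a median of -0.07 (491 to 2133 around -0.46 with values as deposited). Proteasome (21 of 36 lower; -1.15, camera adjusted p = 3.07e-05), oxidative phosphorylation (25 lower, 2 higher; -0.80, 3.07e-05), ribosomal protein (15 lower, 2 higher; -0.60, 7.8e-05), cell cycle (11 of 25 lower; -1.22, 7.84e-05) and secretory genes (9 of 22 lower; -0.89, 9.55e-05) lay lower at the preset correlation, and none kept its call with an estimated correlation (adjusted p = 0.287, 0.343, 0.425, 0.616 and 0.287 with an estimated correlation). Translation factors (6 of 20 lower; -0.73, 0.00277), cholesterol synthesis (8 of 17; -1.07, 0.00438), replication-dependent histones (12 of 51; -0.85, 0.00745) and DNA replication genes (TYMS, PCNA, RRM1, RRM2 and GINS1 of 24; -0.63, 0.0219) did so too, and lost their calls likewise (adjusted p = 0.287, 0.343, 0.714 and 0.714 with an estimated correlation).

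In that order, 23, 30, 23, 14, 9, 9, 9, 13 and 5 members of these 9 lists were lower adjusted over the list alone. Without the doubted array, on which B lymphocyte markers lay at 3.54, the DNA replication list lost its call (-0.25, 0.323), the histone list lay at -0.50 (0.0129) and the cell cycle list at -0.82 (0.00561; adjusted p = 0.754 and 0.563 with an estimated correlation). Proteasome, oxidative phosphorylation, ribosomal protein, secretory, translation factor and cholesterol genes then lay at -1.09, -0.77, -0.68, -0.80, -0.76 and -0.79, and the proteasome and secretory lists passed (adjusted p = 0.03 for each with an estimated correlation). The DNA replication call also ended without total input arrays 2 or 3 (0.0794 and 0.0866). With the date batch as a fixed block the 9 lists lay, in the same order, at -1.33, -0.93, -0.50, -1.49, -1.16, -0.53, -1.38, -1.01 and -1.29. The count of genes was 7203 without T7 control array 2 and 2746 without the doubted array, 4121 with the fixed block, 4815 with the random one and 268 with only the groups compared. Within batch 1 limma called 0, with 1815 at an unadjusted p under 0.05. ELAVL1 mRNA was lower (-1.40, adjusted p = 0.0438), a call lost without any total input array (0.0888, 0.119 and 0.08) or T7 control array 3 (-0.83, 0.174). Without the doubted array it was at -1.97 (0.00252), and PABPC1 mRNA passed (-1.32, 0.00203, against -0.91, 0.0531).

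Each protein was then compared with the mean of the other 3 protein RIPs, which leaves the T7 control out of the difference. In the SLBP RIP, replication-dependent histones were higher in 21 of 51 (23 adjusted over the list alone), led by the linker histone genes H1-5 (17.1-fold, 4.10, SE 0.379, n = 3 and 9 arrays, adjusted p = 1.36e-06) and H1-3 (3.87), at 1.45 relative to all genes (camera adjusted p = 3.53e-09, adjusted p = 0.515 with an estimated correlation). Without SLBP array 3 the shift was 0.38, with 13 higher and 4 lower (0.0162). Small nucleolar RNAs were higher in 66 of 192 and lower in 5 (70 and 5 adjusted over the list alone; 0.89, camera adjusted p = 7.66e-12, adjusted p = 0.0508 with an estimated correlation). Spliceosomal and RNA polymerase III RNAs were higher in 13 of 19 (13 adjusted over the list alone; 1.77, 1.27e-06, adjusted p = 0.515 with an estimated correlation), and ribosomal protein genes higher in 16 and lower in 6 (18 and 7 adjusted over the list alone; 0.54, 0.00367, adjusted p = 0.744 with an estimated correlation; 0.0677 with values as deposited). EPHA6 (4.10, and 3.05 with a common floor), ABCC11 and GCGR rose and SELENOF (-4.46), HSPA13 (-4.26) and ST3GAL5 (-4.25) fell. Counts were 2017 higher and 3605 lower (308 to 5050 with values as deposited and 1212 to 4171 with median centring, around medians of -0.13, -0.78 and -0.29), and 3746 genes without SLBP array 2.

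In the PABPC1 RIP against the other 3, oxidative phosphorylation genes were higher in 40 of 73 and lower in 1, ATP5MC3 (44 and 2 adjusted over the list alone; 0.88, camera adjusted p = 2.07e-11, adjusted p = 0.1 with an estimated correlation). Ribosomal protein genes were higher in 32 and lower in 1, RPS23 (36 and 1; 0.80, 7.21e-10, adjusted p = 0.161 with an estimated correlation) and proteasome genes higher in 19 and lower in 1, PSMB11 (23 and 1; 1.08, 5.53e-08, adjusted p = 0.1 with an estimated correlation). Translation factors (7 higher, 10 adjusted over the list alone; 0.39, 0.00513, adjusted p = 0.161 with an estimated correlation), erythroid (6 higher, 8; 0.63, 0.0368, adjusted p = 0.613 with an estimated correlation) and cholesterol genes (7 higher, 8; 0.57, 0.0368, adjusted p = 0.446 with an estimated correlation) rose. Spliceosomal and RNA polymerase III RNAs (10 of 19 lower, 13 adjusted over the list alone; -2.02, 2.07e-11, adjusted p = 0.161 with an estimated correlation), small nucleolar RNAs (45 lower, 3 higher, 51 and 3; -0.40, 5.53e-08, adjusted p = 0.1 with an estimated correlation) and replication-dependent histones (12 lower, and 1, H2AC25, higher, 13 and 1; -0.75, 6.32e-06, adjusted p = 0.549 with an estimated correlation) fell. The erythroid call ended without PABPC1 array 3 (0.0836), SLBP array 1 (0.054) or SLBP array 3 (0.0534), and the cholesterol call without PABPC1 array 1 (0.0712) or 2 (0.0616). STX8, SGCB, ZNF32, EXOSC5 and MRPL53 rose by 3.87 to 3.35, and SCARNA7 (-5.15), RPL13AP17 (-4.56) and RNU5D-1 (-4.43) fell most, with SGCB at 2.85 and RPL13AP17 at -3.42 under a common floor. PABPC1's own mRNA was higher (0.90, adjusted p = 0.0173), a call lost without PABPC1 array 1 (0.109) or 2 (0.1), and CELF1 mRNA lower (-1.51, 0.000954). Counts were 2532 higher and 1287 lower around a median of 0.14 (6035 to 447 around 0.71 with values as deposited, 5823 to 1698 around 0.37 with median centring), and 2304 genes without PABPC1 array 1.

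In the ELAVL1 RIP against the other 3, oxidative phosphorylation genes were lower in 39 of 73 and higher in 7 (43 and 7 adjusted over the list alone; -1.03, camera adjusted p = 5.18e-10, adjusted p = 0.277 with an estimated correlation) and ribosomal protein genes lower in 23 (26 adjusted over the list alone; -0.55, 2.08e-08, adjusted p = 0.277 with an estimated correlation). Secretory genes were higher in 10 of 22 and lower in 3, P4HB, SSR2 and SSR4 (10 and 3 adjusted over the list alone; 0.70, 0.0451, adjusted p = 0.414 with an estimated correlation), a call lost without SLBP array 1 (0.0552) or 2 (0.0503) and with median centring (0.104). AU-rich mRNAs were higher in 10 of 34 and the rest not called, and the list did not pass (0.0915). Among the largest rises were MIR15A (3.56, and 2.62 with a common floor), SOX1, EXD1 (2.23 with that floor) and ANO5 (2.69), and SATB1 (-4.21, and -3.03 with that floor), GAREM1 (-4.01, -2.91) and TSPAN7 (-3.70) fell most. ELAVL1's own mRNA was higher (1.48, adjusted p = 0.0109), a call lost without ELAVL1 array 2 (0.0564) or 3 (0.0628), and PABPC1 mRNA too (1.09, 0.0066). Counts were 1841 higher and 1670 lower (529 to 824 with values as deposited), and 1645 to 1737 genes without 1 of the ELAVL1 arrays.

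In the CELF1 RIP against the other 3, RBM15B (4.20, SE 0.351), GAREM1 (4.04), NRG1 (3.94 on one probe set and -0.07 on the other), ALG14 (3.73) and PLAU (3.60) rose most, and TMEM42 (-3.85), SLC17A3 (-3.80) and AKR1E2 (-3.78) fell most. CELF1's own mRNA was higher (1.21, SE 0.282, adjusted p = 0.0047), and PABPC1 mRNA lower (-0.77, 0.0357), a call lost in 9 of the single-array omissions (0.0511 to 0.134). Ribosomal protein genes (24 lower, 6 higher; -0.62, camera adjusted p = 0.000558), translation factors (7 of 20 lower; -0.51, 0.009), proteasome genes (13 lower, 4 higher; -0.65, 0.009), cell cycle genes (10 lower, and CDK1, AURKB and PTTG1 higher; -0.75, 0.0118) and small nucleolar RNAs (36 lower, 19 higher; -0.36, 0.0378) fell. They had adjusted p = 0.824, 0.824, 0.824, 0.839 and 0.824 with an estimated correlation, and 29, 8, 15, 10 and 40 members lower adjusted over the list alone. The small nucleolar call ended without CELF1 array 1 (0.0565) or SLBP array 2 (0.0556), with values as deposited (0.252), with median centring (0.19) and with a common floor (0.314). Counts were 2573 higher and 2343 lower (1724 to 2615 with median centring), and 2776 genes without CELF1 array 1. With batch as a random block the 4 comparisons of this kind called 1136 genes for ELAVL1, 1358 for PABPC1, 724 for CELF1 and 4124 for SLBP.

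Calls against the same T7 arrays overlap partly because the controls are shared, and the overlaps were counted with all 3 T7 arrays only. Log2 differences of ELAVL1 and PABPC1 correlated across genes at r = 0.75, ELAVL1 and CELF1 at 0.72, PABPC1 and CELF1 at 0.66, PABPC1 and SLBP at 0.59, ELAVL1 and SLBP at 0.56, and CELF1 and SLBP at 0.53, against 0.89, 0.94, 0.89, 0.81, 0.86 and 0.85 in simulations of unchanged groups. Covariances were 1.45, 1.47, 1.32, 0.89, 0.86 and 0.83, against 0.42 simulated. ELAVL1 and PABPC1 shared 2890 higher genes, where independent lists would share 1129 and simulated unchanged groups 138.6. Higher in all 4 RIPs were 485 genes, and lower 348. Independent lists would give 20.1 and 2.27, and simulated unchanged groups with shared controls gave 110.8 and 112.3, all false calls. Part of the excess may come from the shared controls.

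The authors' deposited region lists give loci in hg19 coordinates with a fold and p of their own. The ELAVL1, PABPC1, CELF1 and SLBP lists hold 3267, 4422, 2268 and 25 regions, of which 70.2%, 60.5%, 73.0% and 40% of probe sets were called higher against T7 here, against 18.7%, 20.1%, 18.9% and 6.10% of all probe sets. The SLBP list held 4 of the 51 replication-dependent histone genes, all on chromosome 6: H1-4 (26156560 to 26157343, authors' fold 3.62), H1-3 (26234441 to 26235242, 3.58), H3C7 (26250370 to 26250835, 2.09) and H1-5 (27834571 to 27835359, 6.04). None of its 25 regions had an authors' adjusted p under 0.05, and the lowest was 0.243, for H1-4.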

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

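The array labelled T7 control replicate 1 looks like RNA of another cell, and its 3 tests were written after the pattern was seen. Its B lymphocyte markers lay 3.54 log2 units above total input, with CD79A at 13.58, PAX5 at 13.21, BLK at 11.89 and CD48 at 11.85. A hypothesis is that the array holds RNA of a B lymphocyte line: erythroid genes lay at -2.43, 8 of 18 at the floor, as RNA of another cell would give, although 9 of the 26 B lymphocyte markers also lay above the median of all genes in K562 total input. Low signal that lifts silent genes was excluded, since hepatocyte markers lay at only 0.22. A swap within the series was not tested by the count of other arrays with such markers (0). An exchange of labels would leave that count unchanged. A genotype or a new hybridisation of that RNA could settle the hypothesis.

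Probe sets stand far apart between groups while the arrays of a group stay together; the 3 tests were written before their results, but the demand for an interval and the minimum of 10 genes were added afterwards. SGCB, for example, had a mean of 12 and an SD of 0.0428 over the T7 arrays and was 6.39 above total input (5.60 with a common floor), and the doubted array goes with its group: 52 of 54 genes far higher in T7 arrays 2 and 3 (96.3%) were also higher on it, and 52 of 57 far lower (91.2%). Within a shared date batch 339 such genes still differed by 2.49 log2 units between T7 array 2 and total input arrays 2 and 3. The 95% interval (2.27 to 2.72) is over genes, with a single T7 array. So date was not the sole source on that array, but a share of date stays open, as does date for PABPC1 and CELF1. RNA sticking to beads was not tested by the count of such genes (0 in total input, 2 in T7), because all RIPs used beads. The first-written bound would have counted it for beads. A hypothesis is that PLIER was run on each group apart, so that a probe set's scale could differ by group: a gene's second probe set followed the first in 77.1% of 157 differences between groups against 80% of 20 within the T7 group, a difference of -2.93 points (-21.7 to 15.8), which leaves it open and under the first-written bound would have counted against it. Running PLIER on all raw arrays together might settle it.

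Histone mRNAs were higher in the SLBP RIP mainly on one array; the tests on SLBP array 3 and on probe sets of several histone genes were written after the values were seen, the date test before, with its interval demand added after. Without SLBP array 3 the shift against the other 3 RIPs was 0.38 instead of 1.45, so that array could carry most of it. Date batch stays open: within batch 1 SLBP arrays 1 and 2 lay 0.50 above T7 array 2 (0.22 to 0.88) and 1.22 above the doubted array, but at -0.15 and -0.09 against total input arrays 2 and 3, and the first-written bound would have counted against date. Separate PLIER runs stay open: probe sets that match several histone genes rose by 1.32 (0.95 to 2.10) against the other 3 RIPs, a value that includes array 3. More SLBP precipitations in one batch could tell whether array 3 is the typical one.

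Calls were recounted over other splits of the same arrays, all 10 for 3 arrays against 3 and 100 drawn at random, the real one included, for the comparisons with the other 3 RIPs, a test written before its results. Against T7 the real split was the highest for ELAVL1 (6712 against at most 0), PABPC1 (6940 against 1815) and CELF1 (6850 against 0), which is 1 of 10 splits with as many calls, and 10 splits are too few for a share under 0.05. For SLBP 2 of 10 splits reached the real count: 4845 genes, against 2492, separated T7 arrays 1 and 3 and SLBP array 3, with 31.2, 16.1 and 13.3% of probe sets at the floor, from T7 array 2 and SLBP arrays 1 and 2 of date batch 1, which points to structure other than the protein; within batch 1 limma called 0, with 1292 unadjusted. Against total input 1 of 10 reached it for ELAVL1 (3249), PABPC1 (3847), CELF1 (4921) and SLBP (1969), each against at most 0 in another split, and 2 of 10 for T7 (3552 against 3879 for total input array 1 with T7 arrays 1 and 3, again the arrays with most values at the floor). Against the other 3 RIPs 1 of 100 splits reached it for ELAVL1 (3511 against 2985, the split of the CELF1 arrays), PABPC1 (3819 against 476), CELF1 (4916 against 2880) and SLBP (5622 against 2903).

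Probe sets without a gene name were not described above. Of 7807 such probe sets 730 were higher and 1395 lower against T7 in the ELAVL1 RIP, 452 and 1767 in PABPC1, 696 and 1342 in CELF1, and 235 and 303 in SLBP. Of 14 histone probe sets that match several genes 6 were higher in the SLBP RIP, with a median of 1.66.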

How the results depend on the processing

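The alternatives changed results as follows, with values in the order in which the settings are named; the cause of the changes was not tested. Of the gene counts 55 moved by more than 1.5 times and 195 did not. Of the list results 985 kept their call and direction, 165 became weaker, 1 stronger and 9 reversed. Of the named-gene results 3783 kept theirs, 172 became weaker, 48 stronger and 52 reversed. A pseudocount was not varied because the values are already log2, and PLIER could not be rerun without raw files.

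With an estimated correlation the AU-rich list in ELAVL1 against T7 stayed at 0.48 (adjusted p = 0.145), the small nucleolar list in PABPC1 against T7 at -1.14 (0.121) and the histone list in SLBP against T7 at 1.65 (0.56). Without the doubted array as well, these shifts were 0.36, -0.77 and 1.24, and B lymphocyte markers lay at 0.37 in PABPC1 and 0.0367 in SLBP. Taking the mean of all probe sets of a gene left the AU-rich list at 0.48 (adjusted p = 0.062).

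With only the groups compared, 2751, 2108, 2914 and 138 genes were called against T7 for ELAVL1, PABPC1, CELF1 and SLBP. Against total input these counts were 6591 for ELAVL1, 7792 for CELF1, 1162 for SLBP and 268 for T7. Against the other 3 RIPs they were 6735, 6968, 8013 and 8878.

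With values as deposited, counts were 11926 for PABPC1 and 5063 for SLBP against T7, 5256 for ELAVL1, 10300 for PABPC1 and 1090 for SLBP against total input, and 1353 for ELAVL1, 6482 for PABPC1 and 2301 for CELF1 against the other 3 RIPs. Directions reversed for CELF1 mRNA (1.67) and SLBP mRNA (2.11) in PABPC1 against T7, for ribosomal proteins there (-0.041), and for CELF1 (0.87) and SLBP mRNA (0.39) in SLBP against T7. Against total input they reversed for CELF1 (1.01) and SLBP mRNA (1.97) in PABPC1, PABPC1 mRNA in CELF1 (0.035), CELF1 (0.21) and SLBP mRNA (0.25) in SLBP and SLBP mRNA in T7 (-0.15), and against the other 3 RIPs for SLBP mRNA in PABPC1 (0.61). This scaling moves all genes together, by medians of 2.28 and 1.09 for PABPC1 and SLBP against T7, 1.81, 1.23 and 0.57 for PABPC1, CELF1 and SLBP against total input, -0.46 for T7 against total input and 0.71 for PABPC1 against the other 3 RIPs. Relative to that median only SLBP mRNA in PABPC1 against total input changed sides among these mRNAs, so the other sign changes say nothing about the gene itself.

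With arrays centred on the median, 6954 genes were called for PABPC1 against total input and 7521 against the other 3 RIPs. Reversed in PABPC1 were SLBP mRNA against T7 (0.41), total input (0.61) and the other 3 RIPs (0.26) and ribosomal proteins against T7 (-0.041). PABPC1 mRNA reversed in CELF1 (-0.035) and SLBP (-0.31) against T7 and in ELAVL1 (-0.048) and PABPC1 (-0.25) against total input. ELAVL1 mRNA did so in SLBP against total input (-0.11). Medians of all genes were then 0.58 and 0.37 for PABPC1 against T7 and the other 3 RIPs. They were 0.02 and -0.16 for SLBP against T7 and total input. Relative to these, SLBP mRNA in the first 2 and PABPC1 and ELAVL1 mRNA in SLBP did not change sides. The other mRNAs did.

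With the date batch as a random block, counts were 2920 for CELF1 and 3806 for SLBP against T7, 1997 for PABPC1 and 1488 for CELF1 against total input, and 1136 for ELAVL1, 1358 for PABPC1 and 724 for CELF1 against the other 3 RIPs. PABPC1 (-0.043) and CELF1 mRNA (0.14) in SLBP against T7 and ELAVL1 mRNA in SLBP against total input (-0.10) reversed. As a fixed block it gave 5048 genes for ELAVL1 against total input, and reversed PABPC1 (-0.21) and CELF1 mRNA (0.39) in SLBP against T7, ELAVL1 mRNA (-0.32) and the histone list (-0.10) in SLBP against total input and SLBP mRNA in T7 against total input (-0.17). Batch 1 alone gave the same 5 values, with 4989 genes for SLBP against total input. It gave 0 limma calls for SLBP against T7, with 1292 unadjusted, and 0 for T7 against total input, with 1815 unadjusted. Without the array labelled T7 control replicate 1, batch 1 gave 3998 genes for SLBP against T7, with CELF1 mRNA at 0.13 and SLBP mRNA at 0.43, from a single T7 array. Batch 2 alone gave 10590 for ELAVL1 against total input, from a single input array.

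Leaving out single arrays gave these ranges, lowest to highest. Counts ran from 1578 to 6518 for SLBP against T7, and against total input from 1886 to 4630 for ELAVL1, 2540 to 5224 for PABPC1, 3198 to 6307 for CELF1, 1148 to 2951 for SLBP and 2479 to 7203 for T7. Against the other 3 RIPs they ran from 1645 to 4922 for ELAVL1, 2304 to 5106 for PABPC1, 2776 to 6211 for CELF1 and 3746 to 7012 for SLBP. List shifts against T7 ran from 0.36 to 0.89 for AU-rich mRNAs in ELAVL1, -1.82 to 0.37 for B lymphocyte markers in PABPC1, -2.08 to 0.0367 for the same in SLBP, -0.015 to 0.46 for ribosomal proteins in SLBP and 0.97 to 1.33 for GU-rich mRNAs in CELF1. The last list gained a call, at 1.02 without the doubted array (adjusted p = 0.0443).

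The proteins' own mRNAs had wide ranges under the same omissions. Against T7, SLBP mRNA ran from -0.10 to 0.75 in ELAVL1 and -0.80 to 0.35 in PABPC1, and in SLBP PABPC1 mRNA from -0.24 to 0.49 and CELF1 mRNA from -0.29 to 0.33. Against total input, SLBP mRNA ran from -0.42 to 0.63 in PABPC1 and -0.11 to 0.74 in T7, and in SLBP CELF1 mRNA from -0.47 to 0.16 and ELAVL1 mRNA from -0.31 to 0.46. Against the other 3 RIPs, ELAVL1 mRNA ran from -0.13 to 0.15 and SLBP mRNA from -0.83 to 0.22 in PABPC1, and CELF1 mRNA from -0.42 to 0.20 in SLBP.

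Replicate numbers do not pair arrays across groups: of 45 pairs with the same number 8 correlated over 0.1, with r from -0.45 to 0.45, and not every array correlated best with its own number. A replicate block gave 6630, 6836, 6757 and 2339 genes against T7, 3044, 3642, 4741, 1825 and 3338 against total input, and 3321, 3605, 4706 and 5450 against the other 3 RIPs.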

Other observations

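Nuclear-encoded oxidative phosphorylation genes lay at -0.94 in the ELAVL1 RIP and at 0.55 in the PABPC1 RIP against total input (adjusted p = 0.343 and 0.754 with an estimated correlation). The T7 control lay at -0.80 against input, and the list did not pass in ELAVL1 against T7 (adjusted p = 0.706). The CELF1 arrays lay at 0.13, -0.05 and -0.06 and the SLBP arrays at -0.22, 0.22 and -0.01, and against the other 3 RIPs the ELAVL1 value was -1.03 (39 of 73 lower, camera adjusted p = 5.18e-10, adjusted p = 0.277 with an estimated correlation).

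Small nucleolar RNAs in PABPC1 against total input lay at -0.79, with all arrays the one list result with an adjusted p under 0.05 with an estimated correlation (0.0474). In SLBP they were higher in 66 of 192 and lower in 5 against the other 3 RIPs, but PABPC1 is part of that reference, the list did not pass against T7 (adjusted p = 0.335), and the SLBP arrays lay at 0.36, 0.39 and -0.11 over total input.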
